A study of Mus musculus with 35 samples.

How the data were processed

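ATAC-seq was done on 10000 cells per library with 13 PCR cycles, per the labels' protocols, in 4 lines of mouse embryonic stem cells at 3 days. The series was analysed from a deposited matrix of 1362779 tiles of 2 kb in 35 libraries. Reads were trimmed with Trim Galore 0.6.5 and cutadapt 2.3 and aligned to GRCm38 with Bowtie2 2.4.1, per the submitters' processing notes. Whether read ends were shifted for the transposase, how duplicates were treated and which regions were masked is not given in the sources used here. The authors deposited log2 RPKM values, the binary logarithm of reads scaled to the length of the tile and the total of the library, per the file headers. In each library the values were whole multiples of 1 read (100% of tiles within a tolerance of 0.01 read), with an empty tile at the value of 0.9 read. The reads behind each value were recovered from these steps, and fold changes of tiles near 0 reads depend on that floor and on depth.

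The recovered reads showed 3 kinds of processing. The sum over tiles was about 1.02 times the library total behind the RPKM in the DNMT lines at D0 and D2, 1.15 times in the TET lines at D0 and D2, and 2.04 times in all lines at D1. D1 libraries held mitochondrial reads (5.62 to 46.8%) and the others none. Of the tiles on autosomes and X, 89649 had no read in any D0 or D2 library, of which 25345 had reads at D1. The day is therefore confounded with processing in D1 against D0, and the family in the parental lines at D0, while knockout and parental line were processed alike within each day. The deposited median of tested tiles shifted by 0.62 in TET_WT from D0 to D1, 0.62 in DNMT_WT, -0.26 in TET_KO against TET_WT at D1, -0.13 at D2 and -0.21 between the parental lines. Changes are reported after quantile normalisation, that is, relative to these shifts.

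The design, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. Tested tiles were those on autosomes and X in the highest 10% by mean log2 RPKM (131688 tiles, minimum -0.55) and every tile with the promoter end of a gene, 137965 in all. They were quantile normalised and fitted with limma 3.58.1 (R 4.3.3) with a mean-variance trend, 1 mean per group of line and day over all 35 libraries (23 residual degrees of freedom, median prior 38.5). Tests were 2-sided with Benjamini-Hochberg adjustment over tiles, genes or lists within a contrast, and a call is an adjusted p under 0.05. There were 13 contrasts: D1 and D2 against D0 in each parental line, knockout against parent at each day, the 2 interactions of line and day, and the parental lines at D0. Groups held 3 libraries, TET_KO at D2 held 2, and no replicate block entered the fit.

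Genes came from an annotation of GRCm38.p6 (21638 genes placed), which gives no strand. The promoter end of a gene was taken as its end with the higher mean accessibility. For 6881 genes (31.8%) the ends differed by under 0.5 log2 units, and these were left out of the promoter readout, a departure from the design made after the data were seen. This rule picks the wrong end for some genes, among them Spi1, Gapdh, Dab2, Hoxb2, Dnmt3a and Esrrb, so the values of Dnmt3a and Esrrb are for tiles around the end far from the promoter. A neighbourhood value is the mean of the tested tiles within 50 kb of the promoter end for which it is the nearest one (21388 genes, median 3 tiles), so a change in a neighbourhood may lie in an element of another gene. Of 270 list genes 269 were matched (Dux was not) in 17 lists: naive, core and formative pluripotency, haematopoietic, primitive streak, neuroectoderm, primitive endoderm, trophoblast, fibroblast, methylation-dependent germline, imprinted, two-cell-like, Hox, MAPK response, Wnt response, methylation machinery and housekeeping genes. Lists were tested with camera at a preset correlation of 0.01 and with an estimated one. Named genes were the 6 targeted genes, up to 4 called genes per list and contrast with the largest change, and the 10 largest rises and falls per contrast among called tiles with groups that did not overlap, 1 per protein-coding gene. A few named genes are not reported here.

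Quantile normalisation distorted the few highest ranks. A small number of tiles with very many reads at D1 only set the shared reference there, so that rank 1 stood at 6.37 against 4.16 without the tiles empty at D0 and D2, rank 10 at 4.22 against 3.49 and rank 15 at 3.47 against 3.37. Among tiles with reads at D0 or D2, 94 reached these 15 ranks in some library, and calls among them numbered from 1 to 13 per contrast. Values of Peg3, Fam72a, Opn3, Crlf2 and Khsrp tiles were among those inflated by this. Where such a value is printed, the value after those tiles were taken out stands beside it.

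Background read density per chromosome was the mean log2 reads over the 1178912 tiles outside the tested set, beside the planned median, which moves in whole reads. Scores of opening and closing tiles used tiles called at least 2-fold in the other parental line and were compared by exact permutation. Depth was 4172681 to 23686796 tile reads per library, 5 to 38 in the median tested tile. Replicates of a group correlated at r of 0.378 to 0.783 across tiles, and their reads differed by 1.12 to 4.04 times sampling noise (chi-square per degree of freedom, tiles of at least 20 reads), so each was counted as a sample. On simulated data for 6 comparisons of 137965 tiles each, the fit called 1.49 to 7.46% of tiles changed 2-fold, 47.8 to 68.7% of those changed 4-fold and 84.8 to 97% of those changed 8-fold, and 2 to 27 unchanged tiles, the most in DNMT_KO at D2. Small changes of single tiles were thus mostly not detectable at this depth.

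Alternatives planned beforehand were the values as deposited, median centring, the highest 5% or 20% of tiles, no filter, a pseudocount of 0.5, a 2-fold minimum, only the groups of a contrast, a replicate block, chromosomes centred on medians, all called tiles for the scores and each library left out. Those added after the data were seen were chromosomes centred on mean density, limma voom on the recovered reads, reads thinned to 3204685 per library, D1 libraries left out, tiles empty at D0 and D2 left out, and a permutation of the change in scores. Corrections for GC content and a test of CpG-island-like tiles were planned but not run, since no genome sequence was used here. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and the R package data.table (version 1.17.8).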

Results

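Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in 35 libraries of mouse embryonic stem cells and of the epiblast-like cells made from them. Cells were kept in the naive state with 2i and Lif (D0) or taken towards the formative state for 1 day (D1) or 2 days (D2). TET_KO cells were a triple knockout of Tet1, Tet2 and Tet3, the enzymes that oxidise 5-methylcytosine, and TET_WT cells were their parental line. DNMT_KO cells lacked Dnmt1, Dnmt3a and Dnmt3b, the DNA methyltransferases, and DNMT_WT cells were the parental line of that family. Each of the 12 groups of line and day held 3 libraries, except TET_KO at D2, which held 2. The question behind the series was how adding and removing DNA methylation shape the exit from pluripotency. The libraries held 4172681 to 23686796 reads in 2-kb tiles, with 5 to 38 reads in the median tested tile. TET_WT at D0 was the deepest group, with 10350700 to 23686796 reads per library, and DNMT_WT at D2 had 4886942 to 5541143. Mitochondrial reads made up 5.62 to 46.8% of each D1 library and 0% of each D0 and D2 library. Accessibility was compared per tile (137965 tested) and per gene neighbourhood, the mean of the tested tiles within 50 kb of the gene's more accessible end (21388 genes). Changes are log2 differences with the standard error of the limma fit, and a call is a 2-sided adjusted p under 0.05. The replicates were not stated to be separate cultures, so the p-values measure the spread between these samples, which may be technical.

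Accessibility over the targeted genes was read first, since a deletion would remove reads from its tiles. At D1, a tile inside Tet1 (chromosome 10, 62812001 to 62814000, GRCm38; gene at 62804570 to 62887469) held 12, 5 and 16 reads in the TET_WT libraries and 0 in each of the 3 TET_KO libraries. The DNMT_WT libraries of the same day held 15, 7 and 4 reads there. The same tile held 0 reads in every D0 and D2 library, wild type included, so it could be read at D1 only. A tile inside Tet3 (chromosome 6, 83372001 to 83374000; gene at 83362373 to 83457208) held 12, 7 and 9 reads in TET_WT at D1 and 1, 0 and 1 in TET_KO. At D0 it held 26, 8 and 13 reads against 1, 2 and 2, and at D2 14, 7 and 18 reads against 2 and 5. No tile of Tet2 (chromosome 3, 133463677 to 133545136) had every TET_KO library at least 2 log2 units below every TET_WT library. No tile of Dnmt1 (chromosome 9, 20907206 to 20959888), Dnmt3a (chromosome 12, 3801559 to 3914443) or Dnmt3b (chromosome 2, 153649411 to 153687730) did so in DNMT_KO. A knockout need not remove a whole tile of sequence, so the DNMT_KO and Tet2 labels could not be checked from accessibility.

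The TET_WT line was compared between D2 and D0 to see which chromatin opened and closed as naive cells became epiblast-like. The neighbourhoods of naive pluripotency genes lost accessibility. Of 21 measured, 6 fell and 0 rose (7 and 0 when adjusted over the list alone), and the list fell as a set (mean -0.32, camera adjusted p = 3.34e-09). Tdh, the threonine dehydrogenase of mouse stem cells (chromosome 14, 63492347 to 63509092), changed by -1.12 ± 0.20, and Tfcp2l1, a transcription factor of the naive network (chromosome 1, 118627923 to 118685168), by -0.88 ± 0.15 (n = 3 and 3). The other falls were those of Tbx3 (-0.72 ± 0.18), Klf5 (-0.63 ± 0.14), Zfp42 (-0.57 ± 0.13) and Nanog (-0.56 ± 0.13), all naive-state transcription factors. Formative epiblast genes opened. 6 of 19 rose and 0 fell (8 and 0 over the list alone; mean 0.50, camera adjusted p = 2.12e-10). They were Fgf5 (1.13 ± 0.30), a growth factor of the epiblast, Dnmt3a (0.98 ± 0.16, read around the gene end far from its promoter) and Dnmt3b (0.79 ± 0.19), the de novo methyltransferases, Pou3f1 (0.90 ± 0.17), Grhl2 (0.89 ± 0.17), a factor of epithelial enhancers, and Zic2 (0.63 ± 0.15). Relative to the mean of all neighbourhoods of a library, the naive list stood at 0.66 ± 0.04 at D0 and 0.29 ± 0.06 at D2 (SD, n = 3), and the formative list at 0.36 ± 0.05 and 0.81 ± 0.08. All 3 libraries of D2 lay beyond all 3 of D0 for both lists, which happens by chance in 10% of such comparisons.

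Other groups of genes moved with the exit from the naive state in TET_WT. Core pluripotency genes shifted up as a set (mean 0.32, camera adjusted p = 0.0017), with 1 of 10 called, Utf1 (0.99 ± 0.15), a chromatin protein of pluripotent cells. Imprinted genes shifted up (mean 0.22, adjusted p = 0.00518), with 1 of 27 called, the non-coding RNA gene H19 (0.92 ± 0.18), which missed the threshold without 1 library (adjusted p = 0.0518 without TET_WT D2 replicate 3). The imprinted list did not pass without a filter on tiles or with thinned reads (highest adjusted p = 0.223). Neuroectoderm genes (mean 0.24, adjusted p = 0.00518) included Pax6 (0.55 ± 0.14) as the 1 call among 14, and the list test gave adjusted p = 0.0708 without TET_WT D2 replicate 2 and 0.0842 with thinned reads. MAPK response genes (mean 0.21, adjusted p = 0.0147) included Spry4 (0.81 ± 0.18), a feedback inhibitor of FGF signalling, as the 1 call among 12. Their test gave adjusted p = 0.0966 without TET_WT D0 replicate 3 and 0.0842 without TET_WT D2 replicate 1, and did not pass with the highest 5% of tiles or thinned reads (adjusted p up to 0.118). Wnt response genes shifted down (mean -0.19, adjusted p = 0.0212), with the feedback gene Axin2 (-0.60 ± 0.12) and the transcription factor Sp5 (-0.99 ± 0.24) called of 12. That test gave adjusted p = 0.0972 without TET_WT D0 replicate 1 and 0.0655 without TET_WT D2 replicate 2 and adjusted p = 0.093 with an estimated correlation. It did not pass as deposited, with chromosomes centred on medians or with thinned reads (adjusted p up to 0.118). The 6 other list tests called in this comparison held with an estimated correlation. Single falls were called for Tfap2c (-0.89 ± 0.15), an AP-2 transcription factor of the trophoblast list, and for the laminin gene Lama1 (-1.12 ± 0.29), and a rise for Twist2 (1.11 ± 0.22) among fibroblast genes. Other lists did not pass as sets: haematopoietic regulators (0 of 25 called, mean 0.17, adjusted p = 0.336), primitive streak and mesoderm (0 of 15 called, mean -0.03, adjusted p = 0.577), primitive endoderm (0 up and 1 down of 14, mean -0.04, adjusted p = 0.486) and trophoblast (0 up and 1 down of 12, mean -0.04, adjusted p = 0.23). Nor did fibroblast (feeder cells) (1 up and 0 down of 14, mean 0.12, adjusted p = 0.398), methylation-dependent germline genes (0 of 23 called, mean 0.18, adjusted p = 0.336) and two-cell-like genes (multi-copy) (0 of 12 called, mean -0.03, adjusted p = 0.766). The same was true of Hox genes (0 of 18 called, mean 0.02, adjusted p = 0.766), methylation machinery (2 up and 0 down of 14, mean 0.18, adjusted p = 0.119) and housekeeping controls (0 of 15 called, mean 0.05, adjusted p = 0.766). The primitive streak list had a median of 0.10 against a mean below 0, and the Hox list a median of -0.09 against a mean above 0.

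By tile, 1558 of 137965 tiles changed in TET_WT from D0 to D2, 505 higher and 1053 lower, of which 1553 changed at least 2-fold (limma, 2-sided). Among the largest rises was a tile inside Plekha1, a phosphoinositide-binding protein (chromosome 7, 130888001 to 130890000; 3.33 ± 0.48; 101 reads over the 3 D2 libraries and 23 over the 3 D0 libraries). Another lay near Shisa6, a protein of glutamate receptors (chromosome 11, 66568001 to 66570000; 2.55 ± 0.38). Among the largest falls was a tile inside Galnt18, a glycosyltransferase (chromosome 7, 111744001 to 111746000; -3.59 ± 0.52; 14 reads at D2 and 185 at D0). A fall lay also 19.3 kb from Foxd3, a forkhead factor of early embryos (chromosome 4, 99636001 to 99638000; -3.05 ± 0.41). In each of these tiles the D2 and D0 libraries did not overlap. The tile count moved by over 1.5 times with some libraries left out, to 784 without TET_WT D0 replicate 1, 727 without replicate 2, 895 without TET_WT D2 replicate 2 and 816 without replicate 3. It ranged from 116 without a filter on tiles to 7155 with limma voom on the recovered reads. Of the 21 list-gene neighbourhoods named, 8 stayed called whichever library was left out (Tdh, Tfcp2l1, Utf1, Pou3f1, Dnmt3a, Grhl2, Tfap2c and Axin2), 3 with reads thinned to 1 depth, 0 on the values as deposited and 0 with only these 2 groups in the fit. Nanog, Tbx3, Fgf5 and Pax6 stayed called only without TET_WT D0 replicate 3, and Lama1 in no such fit.

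**Figure D1:**
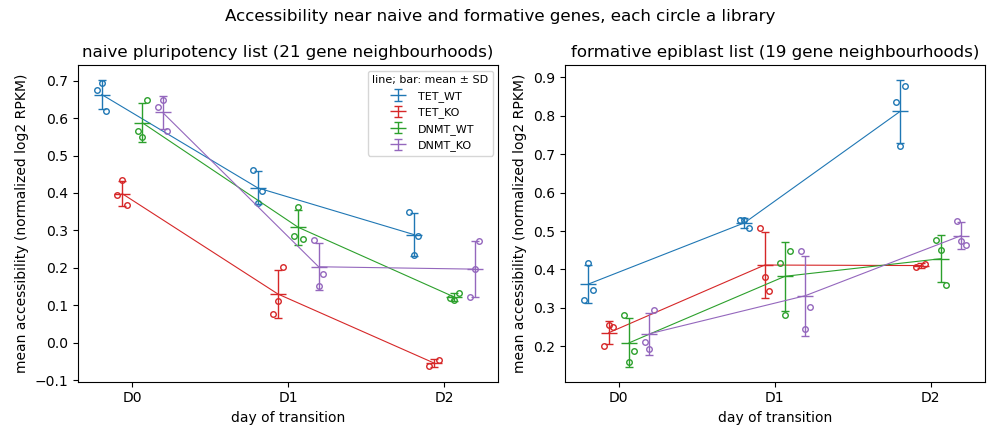
Mean accessibility of the naive pluripotency and formative epiblast neighbourhoods (log2 RPKM, relative to the mean of all neighbourhoods of the same library) by day, 1 point per library, with group mean and SD. In TET_WT the naive list goes from 0.66 at D0 to 0.29 at D2 and the formative list from 0.36 to 0.81.

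The same comparison in the DNMT_WT line asked whether another parental line makes the same moves. Naive pluripotency neighbourhoods fell again. 6 of 21 fell and 0 rose (9 and 0 over the list alone; mean -0.41, camera adjusted p = 2.57e-10). Esrrb, an orphan nuclear receptor of the naive state (chromosome 12, 86361117 to 86521628), changed by -0.97 ± 0.17 around the gene end far from its promoter, Tfcp2l1 by -0.92 ± 0.15, Klf5 by -0.70 ± 0.14 and Zfp42, also known as Rex1, by -0.69 ± 0.13. All 4 kept their call whichever library was left out. Tdh changed by -0.94 ± 0.20 and was lost without 1 of 2 libraries (adjusted p = 0.0551 without DNMT_WT D0 replicate 3 and 0.0538 without DNMT_WT D2 replicate 3), and Tbx3 (-0.68 ± 0.18) was called with all libraries only. Of formative neighbourhoods 3 of 19 rose and 0 fell (7 and 0 over the list alone; mean 0.28, adjusted p = 0.00362). They were Dnmt3b (0.90 ± 0.19), Pou3f1 (0.77 ± 0.17) and Dnmt3a (0.61 ± 0.16, read around its far end), each lost in most fits without 1 library. Relative to all neighbourhoods, the naive list went from 0.59 ± 0.05 to 0.12 ± 0.01 (SD, n = 3) and the formative list from 0.21 ± 0.06 to 0.43 ± 0.06, with all 3 D2 libraries beyond all 3 D0 libraries in each. Trophoblast genes fell as a set (mean -0.23, adjusted p = 0.0029), with Tfap2c (-0.94 ± 0.15) and Tead4 (-0.56 ± 0.14), a partner of Yap, called of 12. Utf1 rose by 1.02 ± 0.15, while Msgn1, a factor of the presomitic mesoderm (-1.06 ± 0.19), and the imprinted zinc finger gene Plagl1 (-0.97 ± 0.19) fell.

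MAPK response genes in DNMT_WT had 2 of 12 called, the immediate early gene Egr1 (0.86 ± 0.19) and Spry4 (0.69 ± 0.18). Their mean was 0.25 (camera adjusted p = 0.0381; adjusted p = 0.0566 with an estimated correlation). The test did not pass in 4 of the 6 fits without 1 library (adjusted p = 0.0741 without DNMT_WT D0 replicate 1, 0.0569 without replicate 2, 0.0545 without DNMT_WT D2 replicate 1 and 0.111 without replicate 3). The primitive endoderm test (mean -0.15, adjusted p = 0.0443; adjusted p = 0.0963 with an estimated correlation; 0 of 14 called) did not pass in 5 of those fits (adjusted p = 0.0741 without DNMT_WT D0 replicate 1, 0.15 without replicate 3, 0.0549 without DNMT_WT D2 replicate 1, 0.0797 without replicate 2 and 0.0644 without replicate 3). Of the alternative settings 9 of 13 passed for MAPK response genes (adjusted p up to 0.221) and 8 of 13 for primitive endoderm genes (adjusted p up to 0.249). Core pluripotency genes, with Utf1 and Zfp281 called of 10, did not pass as a set (mean 0.26, adjusted p = 0.051). The methylation machinery list had 3 of 14 up, Dnmt3a at its far end, Dnmt3b and the methyl-CpG binding gene Mbd2 (0.63 ± 0.16), with adjusted p = 0.697. The remaining 10 lists had adjusted p of 0.0701 or more, and Sp5 (-1.08 ± 0.24) was the 1 call among Wnt response genes. By tile, 3355 changed, 867 higher and 2488 lower (3336 at least 2-fold). With the values as deposited 14% of 2210 calls were higher, against 25.8%. The largest fall lay inside Tnfrsf21, a death receptor (chromosome 17, 43036001 to 43038000; -4.29 ± 0.38; limma adjusted p = 1.29e-11; 4 reads over the D2 libraries and 116 over the D0 libraries). Tiles near Trps1, a GATA-type repressor (chromosome 15, 50900001 to 50902000; -3.66 ± 0.41) and near Nrp2, a semaphorin receptor (chromosome 1, 62678001 to 62680000; -3.31 ± 0.48), fell as well. A rise lay 9.89 kb from Utf1 (chromosome 7, 139954001 to 139956000; 2.99 ± 0.49). Without DNMT_WT D0 replicate 1 or 2 the tile count was 2052 or 2105, and it ranged from 526 with thinned reads to 3355 as reported. Of the 19 list-gene neighbourhoods named, 8 kept their call whichever library was left out, 8 with thinned reads, 2 as deposited and 0 with only these 2 groups in the fit.

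The parental lines share no libraries, so their calls could be overlapped directly. From D0 to D2, 121 tiles rose in both lines (3.17 in independent lists) and 575 fell in both (19), while 0 moved in opposite directions. The tiles inside Plekha1 and near Shisa6 rose in both, the latter by 2.55 ± 0.38 in TET_WT and 2.95 ± 0.38 in DNMT_WT. Of the tiles called higher in TET_WT, 91.5% had the same sign in DNMT_WT with a median of 0.92, and of those called lower 98.4% with a median of -1.48. The log2 changes of the lines correlated across tiles with Pearson's r of 0.39 and Spearman's rho of 0.31; tiles are not independent replicates. Promoter ends made up 1.52% of tiles lower in TET_WT and 3.14% in DNMT_WT, and 9.31 and 16.5% of those higher. Fisher's exact test (2-sided, adjusted over 20 tests) gave p = 3.53e-49, 2e-81, 0.00124 and 0.205. The reference in each, 14.6% of tested tiles, holds promoter tiles below the 10% filter, so 9.31% need not be a lack. Neighbouring tiles are not independent, so these p are too small.

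The first day of the exit was compared with D0 in each parental line. In DNMT_WT, naive neighbourhoods shifted down (mean -0.25, camera adjusted p = 9.22e-05), with Tdh (-0.98 ± 0.20), the cofactor gene Tcl1 (-0.83 ± 0.21) and Tfcp2l1 (-0.75 ± 0.15) called of 21 and 0 up (3 and 0 over the list alone). Core pluripotency genes shifted up (mean 0.41, adjusted p = 9.22e-05; 1 of 10 called and 4 over the list alone), led by Utf1 (0.95 ± 0.15). MAPK response genes shifted up too (mean 0.34, adjusted p = 0.000473; 3 of 12 called, 4 up and 1 down over the list alone), with Spry4 (1.06 ± 0.18), the ERK phosphatase Dusp6 (0.80 ± 0.18) and Myc (0.64 ± 0.12). Formative genes had 1 of 19 called, Grhl2 (0.78 ± 0.17), and a mean of 0.21 (adjusted p = 0.00754; 0.0513 without DNMT_WT D1 replicate 3; adjusted p = 0.0625 with an estimated correlation). In TET_WT, the naive list fell (mean -0.19, adjusted p = 0.0011; 0 of 21 called, 3 down and 1 up over the list alone). The formative list rose (mean 0.22, adjusted p = 0.0046; adjusted p = 0.0655 with an estimated correlation; 0 of 19 called, 4 over the list alone). Core pluripotency (mean 0.20, adjusted p = 0.0499; adjusted p = 0.186 with an estimated correlation) and primitive streak genes (mean -0.17, adjusted p = 0.0302; adjusted p = 0.0743 with an estimated correlation) passed narrowly. Without TET_WT D0 replicate 3 or D1 replicate 1 they did not (0.286 without TET_WT D0 replicate 3 and 0.339 without TET_WT D1 replicate 1; 0.0611 without TET_WT D0 replicate 3 and 0.061 without TET_WT D1 replicate 1). Its 3 called list genes were Utf1 (0.73 ± 0.15), Spry4 (0.89 ± 0.18) and Tfap2c (-0.83 ± 0.15). Tfap2c was lost without 1 of 2 libraries (adjusted p = 0.085 without TET_WT D0 replicate 1 and 0.0755 without TET_WT D1 replicate 3), while Utf1 was kept only without TET_WT D0 replicate 2 or D1 replicate 3, and Spry4 only without D1 replicate 2 or 3. On the values as deposited the naive test did not pass in either line (TET_WT mean 0.46, adjusted p = 0.876; DNMT_WT adjusted p = 0.165). Of the alternative settings 9 of 12 passed for formative genes in DNMT_WT (adjusted p up to 0.0993), and in TET_WT 11 of 12 for formative (up to 0.0585), 7 of 12 for core pluripotency (up to 0.278) and 7 of 12 for primitive streak genes (up to 0.509).

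By tile, 519 changed by D1 in TET_WT (258 higher and 261 lower) and 1683 in DNMT_WT (681 and 1002). Of these, 66 rose in both lines (1.27 in independent lists) and 108 fell in both (1.9). A tile near Nrp2 fell in TET_WT (-2.57 ± 0.48; 26 reads at D1 and 273 at D0) and in DNMT_WT (-2.94 ± 0.48; 20 and 183). Others fell near S1pr1, a sphingosine phosphate receptor (chromosome 3, 115694001 to 115696000), at -3.50 ± 0.46 in DNMT_WT, and inside the scaffold gene Nedd9 (chromosome 13, 41458001 to 41460000; -2.95 ± 0.45) in TET_WT. Large rises lay in tiles with no reads at all outside D1. A tile 25.1 kb from Col19a1 (chromosome 1, 24612001 to 24614000) held 26167 reads over the TET_WT D1 libraries, 38768 over those of DNMT_WT and 0 in every D0 and D2 library. In all, 30 of the higher calls of TET_WT and 50 of those of DNMT_WT lay in tiles empty in every D0 and D2 library, so the D1 libraries had been processed differently and their changes against D0 cannot be told apart from that difference. On the values as deposited 99.5% of 5868 TET_WT calls and 97.3% of 8868 DNMT_WT calls were higher, where the median tile lay 0.62 log2 units above D0 in both lines, and after median centring 61.3% of 186 in TET_WT. The TET_WT count was 210 without TET_WT D0 replicate 1, 175 without replicate 2, 242 without TET_WT D1 replicate 2 and 219 without replicate 3, and the DNMT_WT count 920 (493 higher) without DNMT_WT D0 replicate 1, 857 (428) without replicate 2 and 1021 (356) without DNMT_WT D1 replicate 3. With thinned reads the counts were 77 and 155.

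Loss of the 3 TET enzymes was compared with TET_WT at each day. At D0, 3 of 21 naive neighbourhoods fell and 0 rose (5 and 1 over the list alone; mean -0.16, camera adjusted p = 0.0227): Klf5 (-0.63 ± 0.14), Zfp42 (-0.59 ± 0.13) and Klf2 (-0.58 ± 0.16). Zfp42 and Klf2 lie on chromosome 8 and Klf5 on chromosome 14, where TET_KO cells had fewer background reads: -0.45 log2 units against TET_WT on chromosome 8 and -0.36 on chromosome 14. With each chromosome centred on its background density the values were -0.26, -0.15 and -0.13, none of them called. The same holds for Otx2, a homeobox gene of the formative epiblast on chromosome 14 (-0.81 ± 0.16, then -0.43), and Sox1, a neural factor on chromosome 8 (-0.82 ± 0.16, then -0.37). Olig2, a basic helix-loop-helix factor of neural progenitors (chromosome 16, 91225550 to 91228677), was lower in both versions (-0.76 ± 0.15, then -0.88), and Mael, a germline gene of the piRNA pathway (chromosome 1, 166201385 to 166238744), was higher in both (1.67 ± 0.33, then 1.57). Olig2 was lost without 1 library (adjusted p = 0.0522 without TET_WT D0 replicate 1) and Mael without 1 of 2 (0.063 without TET_WT D0 replicate 1 and 0.0659 without replicate 2). Higher calls among imprinted genes were H19 (0.96 ± 0.18, then 0.77 and not called), Zdbf2 (0.51 ± 0.14) and Peg3, whose 1.55 became 0.98 once tiles with reads at D1 only were taken out before normalisation. The other 16 lists had adjusted p of 0.0601 or more, the germline genes that promoter methylation silences among them (1 of 23 up and 1 down, mean 0.26, adjusted p = 0.253). The naive test did not pass after median centring (adjusted p = 0.0874), with chromosomes centred on medians or with thinned reads (0.17). It passed after density centring (0.0475), and over all settings p ranged from 0.00227 to 0.17.

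By tile, 349 differed between TET_KO and TET_WT at D0, 160 higher and 189 lower, and 147 of the 189 lower tiles lay on chromosome 8. After density centring 84 were called, of which 66.7% were higher, against 45.9% before. A tile near Stac2, an adaptor protein of calcium channels (chromosome 11, 98066001 to 98068000), was lower, at -3.07 ± 0.38 (12 reads over 3 TET_KO libraries and 179 over 3 TET_WT libraries; limma adjusted p = 8.01e-07), and at -2.99 after density centring. A tile inside Spire2, an actin nucleator on chromosome 8 (-2.71 ± 0.38, then -2.27), was lower too, and a tile near the sulfotransferase gene Sult3a2 (chromosome 10, 33796001 to 33798000) was higher (2.61 ± 0.38, then 2.53). These tiles were picked among called tiles whose TET_KO and TET_WT libraries did not overlap, and 11 of the 20 named tiles stayed called after density centring. The count was 57 (34 higher) without TET_WT D0 replicate 1, 52 (26) without replicate 2, 675 (400) without replicate 3, 166 (53) without TET_KO D0 replicate 2 and 119 (35) without replicate 3, and ranged from 11 with thinned reads to 2534 (1416 higher) with limma voom. The share of higher calls was 27.8% as deposited, 33.9% median-centred and 71% with chromosomes centred on medians.

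**Figure D2:**
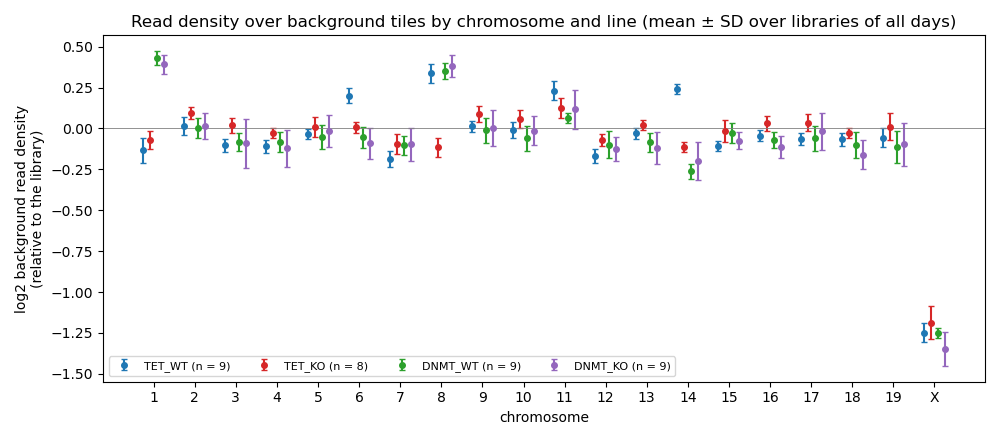
Log2 read density over background tiles by chromosome for the 4 lines, mean and SD over the libraries of all days. Chromosome 8 stands at -0.11 in TET_KO and 0.34 in TET_WT, and chromosome 1 at 0.43 in DNMT_WT and -0.13 in TET_WT.

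At D1, 5 of 21 naive neighbourhoods were lower in TET_KO and 0 higher (5 and 0 over the list alone; mean -0.20, camera adjusted p = 0.000244; 0.000383 after density centring). They were Nanog (-0.71 ± 0.13), the homeobox factor of the naive state, Tdh (-0.86 ± 0.20), Klf5 (-0.70 ± 0.14), Klf2 (-0.70 ± 0.16) and Zfp42 (-0.64 ± 0.13). Density centring left them at -0.53, -0.50, -0.37, -0.21 and -0.16, without a call. The promoter end of Nanog was lower, at -1.76 ± 0.32 and at -1.59 after density centring, still called, though not without 1 library (adjusted p = 0.091 without TET_KO D1 replicate 3). MAPK response genes were lower as a set (mean -0.25, adjusted p = 0.0024; 1 of 12 down and 2 over the list alone), the 1 call being Spry2 on chromosome 14 (-0.65 ± 0.14, then -0.32). That test did not pass with thinned reads (adjusted p = 0.0624), the highest 20% of tiles or no filter (adjusted p up to 0.187). Naive promoter ends were lower as a set (mean -0.21, camera adjusted p = 0.0196; 0.196 with an estimated correlation; 1 of 18 called). That test passed in 8 of 12 settings and not without TET_WT D1 replicate 3 or TET_KO D1 replicate 1 (adjusted p up to 0.192). Beside these groups, fibroblast genes, the markers of feeder cells, were higher at their promoter ends (mean 0.60, camera adjusted p = 0.0196; 0.189 with an estimated correlation; 0 of 10 called, 2 over the list alone). The promoter test gave adjusted p = 0.0621 without TET_WT D1 replicate 1, 0.103 without replicate 3 and 0.0938 without TET_KO D1 replicate 2 and 0.289 with thinned reads. As neighbourhoods the fibroblast list stood at 0.03 ± 0.14 in TET_KO and -0.21 ± 0.20 in TET_WT (SD, n = 3 and 3; camera adjusted p = 0.186). Zic2 (-0.63 ± 0.15) and Zic5 (-0.62 ± 0.14), neighbours on chromosome 14, were the 2 of 19 formative genes called, and the other 15 lists had adjusted p of 0.173 or more. By tile, 165 differed (78 higher and 87 lower), 69 after density centring. The tile near Stac2 was lower again (-2.62 ± 0.38), as was a tile near the apolipoprotein gene Apod (chromosome 16, 31326001 to 31328000; -3.17 ± 0.42; 13 reads against 107). The promoter end of Aspg, an asparaginase (chromosome 12, 112106001 to 112108000; 2.09 ± 0.37), was higher. The count was 85 (57 higher) without TET_WT D1 replicate 1, 78 (51) without replicate 3, 252 (83) without TET_KO D1 replicate 1 and 109 (42) without replicate 3, and ranged from 40 with thinned reads to 2249 without a filter on tiles. The share of higher calls was 47.3%, 12.2% of 263 as deposited, 66.7% after density centring and 69.2% with chromosomes centred on medians.

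At D2, with 2 TET_KO libraries, formative, naive and MAPK response neighbourhoods were lower in TET_KO. Of 19 formative genes 3 were lower and 0 higher (5 and 0 over the list alone; mean -0.29, camera adjusted p = 5.18e-06): Zic2 (-0.80 ± 0.17), Zic5 (-0.79 ± 0.15) and Etv5 (-0.73 ± 0.18), an ETS factor downstream of FGF. Of 21 naive genes 2 were lower (6 over the list alone; mean -0.23, adjusted p = 3.05e-05), Klf2 (-0.81 ± 0.18) and Zfp42 (-0.76 ± 0.15). Of 12 MAPK response genes 3 were lower (5 over the list alone; mean -0.33, adjusted p = 2.38e-05), among them the phosphatase gene Dusp4 (-0.94 ± 0.20) and Spry2 (-0.68 ± 0.16). These 3 list tests passed with an estimated correlation and after density centring (6.51e-07, 0.000318 and 4.27e-06), whereas 0 of the 11 single genes did: Etv5 had -0.83, Zic2 -0.49 and Klf2 -0.36. Relative to all neighbourhoods, the formative list stood at 0.41 ± 0.01 in TET_KO (SD, n = 2) and 0.81 ± 0.08 in TET_WT (n = 3), with 2 of 2 below 3 of 3. Core pluripotency (mean -0.23, adjusted p = 0.00969) and methylation machinery genes (mean -0.18, adjusted p = 0.00969) were lower, and fibroblast genes higher (mean 0.55, adjusted p = 0.00969; 1 of 14 called, the calcium-binding gene S100a4 at 1.97 ± 0.44). With an estimated correlation these had adjusted p = 0.114, 0.0535 and 0.114, and the fibroblast test gave adjusted p = 0.101 without TET_KO D2 replicate 1. The core pluripotency test did not pass without a filter on tiles (adjusted p = 0.0883), nor the fibroblast test with thinned reads (adjusted p = 0.233). At promoter ends the naive (-0.25), core (-0.27), formative (-0.17) and fibroblast (0.58) tests each had camera adjusted p = 0.0466, and 0.17 with an estimated correlation, with 0 genes called. They passed in 6, 7, 4 and 6 of 13 settings (adjusted p up to 0.739, 0.325, 0.325 and 0.325). The naive test did not pass without TET_WT D2 replicate 2 or TET_KO D2 replicate 3 (adjusted p up to 0.213) and the core test without any 1 library (up to 0.13). The formative test passed only without TET_WT D2 replicate 3 (otherwise up to 0.128) and the fibroblast test only without TET_KO D2 replicate 1 (otherwise up to 0.213). The other 11 lists had adjusted p of 0.168 or more. Each single-gene call was kept only without TET_WT D2 replicate 2, except those of S100a4 and Spry2, which were lost in all 5 fits without 1 library.

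By tile, 149 differed at D2, 34 higher and 115 lower, and 71 of the lower tiles lay on chromosome 8. After density centring 48 were called. A tile near the zinc finger gene Zfp640 (chromosome 13, 66710001 to 66712000) was lower, at -3.07 ± 0.38 (15 reads over 2 TET_KO libraries and 202 over 3 TET_WT libraries), and at -3.19 after density centring. Tiles near Apod (-2.82 ± 0.47), near Trps1 (-3.01 ± 0.45) and inside Pitpnc1, a phosphatidylinositol transfer protein (chromosome 11, 107436001 to 107438000; -3.63 ± 0.49), were lower too. The first was lost without TET_KO D2 replicate 3 and the second, which also fell in DNMT_WT, without replicate 1. Promoter ends made up 3.48% of the lower tiles (Fisher's exact test, adjusted p = 0.000488) and, at D1, 38.5% of the higher ones (adjusted p = 6.99e-07). The D2 count was 50 without TET_WT D2 replicate 1, 68 without replicate 3, 78 without TET_KO D2 replicate 1 and 394 without replicate 3, and ranged from 16 with only these groups in the fit to 330 with limma voom. Most calls were then higher, 12 of the 16 and 220 of the 330, so the balance towards lower tiles depends on the fit. Calls of different days overlapped, with 13 tiles higher and 12 lower at both D0 and D1, 14 and 8 at D0 and D2, and 8 and 5 at D1 and D2, against 0.158 or fewer in independent lists, and the days share no libraries.

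Whether the change from D0 to D2 differed between TET_KO and TET_WT was tested as an interaction. Formative neighbourhoods gained less in TET_KO (mean -0.27, camera adjusted p = 0.000326; 0.0252 with an estimated correlation; 0 of 19 called by either adjustment). Over the alternative settings the adjusted p was 0.00011 to 0.166, the highest without a filter on tiles and the 1 that did not pass. The list went from 0.24 ± 0.03 to 0.41 ± 0.01 in TET_KO and from 0.36 ± 0.05 to 0.81 ± 0.08 in TET_WT, relative to all neighbourhoods (SD). Methylation machinery (mean -0.22, adjusted p = 0.0149) and core pluripotency genes (mean -0.21, adjusted p = 0.035) had adjusted p = 0.0696 and 0.196 with an estimated correlation. The first gave adjusted p = 0.0596 without TET_WT D0 replicate 3, 0.0937 without TET_KO D0 replicate 2 and 0.0576 without TET_KO D2 replicate 3. The second did not pass in 6 of 11 fits (0.259 without TET_WT D0 replicate 3, 0.198 without TET_WT D2 replicate 1, 0.0552 without TET_KO D0 replicate 1, 0.0937 without replicate 2, 0.102 without TET_KO D2 replicate 1 and 0.0576 without replicate 3). Of the alternative settings 9 of 13 and 6 of 13 passed. For naive genes the interaction was -0.08 (adjusted p = 0.331), and 0 neighbourhoods were called (limma; 667 at an unadjusted p under 0.05). By tile 3 were lower and 0 higher, near Trps1 (-3.75 ± 0.61), inside Pitpnc1 (-3.59 ± 0.66) and inside Peg3 (-2.30 ± 0.33, or -0.66 without the tiles read at D1 only), with 4653 tiles at an unadjusted p under 0.05 and 1 called by limma voom. The count was 1 without TET_WT D0 replicate 2, 1 without TET_KO D0 replicate 3, 1 without TET_KO D2 replicate 1 and 14 without replicate 3. To score the exit without shared libraries, tiles called at least 2-fold in DNMT_WT were read in the TET lines. The 857 opening tiles stood at -0.05 ± 0.03 in TET_KO and -0.21 ± 0.05 in TET_WT at D0 (SD, n = 3 and 3), at 0.48 ± 0.06 and 0.31 ± 0.05 at D1, and at 0.59 ± 0.02 (n = 2) and 0.52 ± 0.09 at D2. The 2-sided exact permutation p was 0.1, 0.1 and 0.5, of which 0.1 is the smallest these designs allow. On the values as deposited the opening differences, 0.16, 0.17 and 0.08, were 0.03, -0.08 and -0.06, so that those of D1 and D2 turned their sign. For the 2479 closing tiles the differences were 0.04, -0.13 and -0.10 (exact p = 0.8, 0.3 and 0.4). As deposited those of D1 and D2 were -0.41 and -0.26 (exact p = 0.1 and 0.2). From D0 to D2 the gain of opening tiles differed by -0.08 (exact p = 0.485 over 200 arrangements) and the loss of closing tiles by -0.14 (p = 0.385). The latter was -0.31 as deposited, -0.28 median-centred, -0.24 without TET_WT D0 replicate 3 and -0.07 without TET_WT D2 replicate 2.

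Loss of the 3 DNA methyltransferases was compared with DNMT_WT at each day, and few regions differed. Imprinted genes, whose expression from 1 parental copy rests on DNA methylation, were more accessible at their promoter ends in DNMT_KO at D2 (mean 0.31, camera adjusted p = 0.00219; 0.013 with an estimated correlation; 0 of 25 called, 2 up and 0 down over the list alone). Without DNMT_KO D2 replicate 3 the p was 0.0656. At D0 they were higher at promoter ends (mean 0.25, adjusted p = 0.0222; adjusted p = 0.0593 with an estimated correlation) and as neighbourhoods (mean 0.17, adjusted p = 0.037; 0 of 27 called, 1 over the list alone). The promoter test gave adjusted p = 0.125 without DNMT_WT D0 replicate 3, 0.104 without DNMT_KO D0 replicate 2 and 0.132 without replicate 3. The neighbourhood test gave adjusted p = 0.183 without DNMT_WT D0 replicate 1, 0.218 without replicate 3, 0.0604 without DNMT_KO D0 replicate 1, 0.118 without replicate 2 and 0.137 without replicate 3, and 0.29 without a filter on tiles, 0.254 with thinned reads and 0.0553 without the tiles empty at D0 and D2. Germline genes silenced by promoter methylation did not pass at D0 (mean 0.09, adjusted p = 0.528), D1 (0.00; 0.899) or D2 (0.15; 0.267), with 0 of 23 called at each day, and at D1 the test pointed down while the mean stood above 0. At their promoter ends the means were 0.21, 0.06 and 0.23 (adjusted p = 0.111, 0.957 and 0.172; 0 of 20 called). Nor did naive genes (mean 0.02, -0.04 and 0.06) or formative genes (0.02, 0.01 and 0.04), and the lowest p of any other neighbourhood test of a list was 0.14. At D2, 39 tiles were called (13 up, 26 down). Simulation with planted changes called 27 unchanged ones, so an unknown share may be false. A tile inside Ccdc3 (chromosome 2, 5140001 to 5142000) was higher by 2.69 ± 0.49 (31 reads against 3). A tile near Ncam2 (chromosome 16, 81174001 to 81176000) was lower, at -2.96 ± 0.52 (5 against 32). The first missed the threshold without 1 of 2 libraries (limma adjusted p = 0.0839 without DNMT_WT D2 replicate 1 and 0.0553 without DNMT_KO D2 replicate 2), as did the second (0.0945 without DNMT_WT D2 replicate 2 and 0.091 without DNMT_KO D2 replicate 2). The D2 count was 77 (50 higher) without DNMT_WT D2 replicate 1 and 22 (14) without replicate 2, which turned the direction of most calls, and 1 with thinned reads, 1 with limma voom and 0 without a filter on tiles.

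At D1, 58 tiles differed between DNMT_KO and DNMT_WT, 41 higher and 17 lower. The DNMT_KO libraries of D1 had the lowest correlations between replicates of any group (r of 0.378 to 0.478; chi-square per degree of freedom 2.37 to 4.04), and 26.1 and 22.4% of all tiles were empty in replicates 2 and 3 (18.4% or less in the other groups). The tile near Rbpms2, an RNA-binding protein (chromosome 9, 65618001 to 65620000), was lower, at -2.30 ± 0.42 (1 read over 3 DNMT_KO libraries and 24 over 3 DNMT_WT libraries). List genes called were the imprinted non-coding gene Meg3 (0.74 ± 0.18), the Wnt antagonist Notum (0.89 ± 0.19) and the homeobox gene Cdx1 (-0.92 ± 0.22), and 0 of the 3 were called with thinned reads. Meg3 and Cdx1 were lost in 5 of the 6 fits without 1 library and Notum in 4. Among all neighbourhoods 514 were called at D1, but 3 with thinned reads and 0 without the tiles empty at D0 and D2, and 82.9% of the higher tiles were promoter ends. The tile count was 90 (78 higher) without DNMT_WT D1 replicate 3, 900 (653) without DNMT_KO D1 replicate 1, 144 (48) without replicate 2 and 121 (51) without replicate 3, 0 with limma voom, 3 with thinned reads and 82393 without a filter on tiles. The share of higher calls was 70.7%, 10.6% of 104 as deposited, 8.78% of 467 median-centred, 50% after density centring and 58.6% with chromosomes centred on medians. At D0, 1 tile was lower and 0 higher, at the promoter end of Fam72a (-1.99 ± 0.26), which without the tiles read at D1 only was -0.53 and not called (7933 tiles at an unadjusted p under 0.05 with limma, 1 called by limma voom). That count was 3 without DNMT_WT D0 replicate 1, 5 without replicate 3, 3 without DNMT_KO D0 replicate 1, 4 without replicate 2 and 3 without replicate 3. By neighbourhood, 0 genes were called at D0 and 0 at D2 (limma; 1225 and 1760 at an unadjusted p under 0.05).

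The exit from the naive state in DNMT_KO was scored with tiles called at least 2-fold in TET_WT. The 504 opening tiles stood at 0.27 ± 0.09 in DNMT_KO and 0.67 ± 0.09 in DNMT_WT at D2 (SD, n = 3 and 3), a difference of -0.40 with 3 of 3 DNMT_KO libraries below all DNMT_WT libraries (2-sided exact permutation p = 0.1, the smallest 3 against 3 allow). At D0 they stood at -0.37 ± 0.05 and -0.30 ± 0.09 (exact p = 0.3), and at D1 at 0.37 ± 0.22 and 0.44 ± 0.08 (exact p = 0.8). The 1049 closing tiles, for which no p could pass either, stood at 1.00 ± 0.05 and 1.05 ± 0.03 at D0 (exact p = 0.2) and were compared at D1 (exact p = 0.9) and D2 (-0.49 ± 0.02 and -0.45 ± 0.06; exact p = 0.4). Their differences of -0.04 at D0, 0.01 at D1 and -0.04 at D2 turned to 0.07, -0.06 and 0.02 as deposited, and to 0.01 at D0 and -0.12 at D1 median-centred. The gain of opening tiles from D0 to D2 differed by -0.33 between the lines (exact p = 0.105 over 400 arrangements, 2-sided), and the loss of closing tiles by 0.00 (p = 0.97). In the interaction of line and day, 0 neighbourhoods (1219 at an unadjusted p under 0.05 with limma) and 1 tile were called, and 0 tiles without those read at D1 only. There were 8633 tiles at an unadjusted p under 0.05, and limma voom called 0. The count was 2 without DNMT_WT D0 replicate 1, 3 without DNMT_WT D2 replicate 1 and 2 without DNMT_KO D0 replicate 1. The lowest camera adjusted p of any list in this interaction was 0.363.

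**Figure D3:**
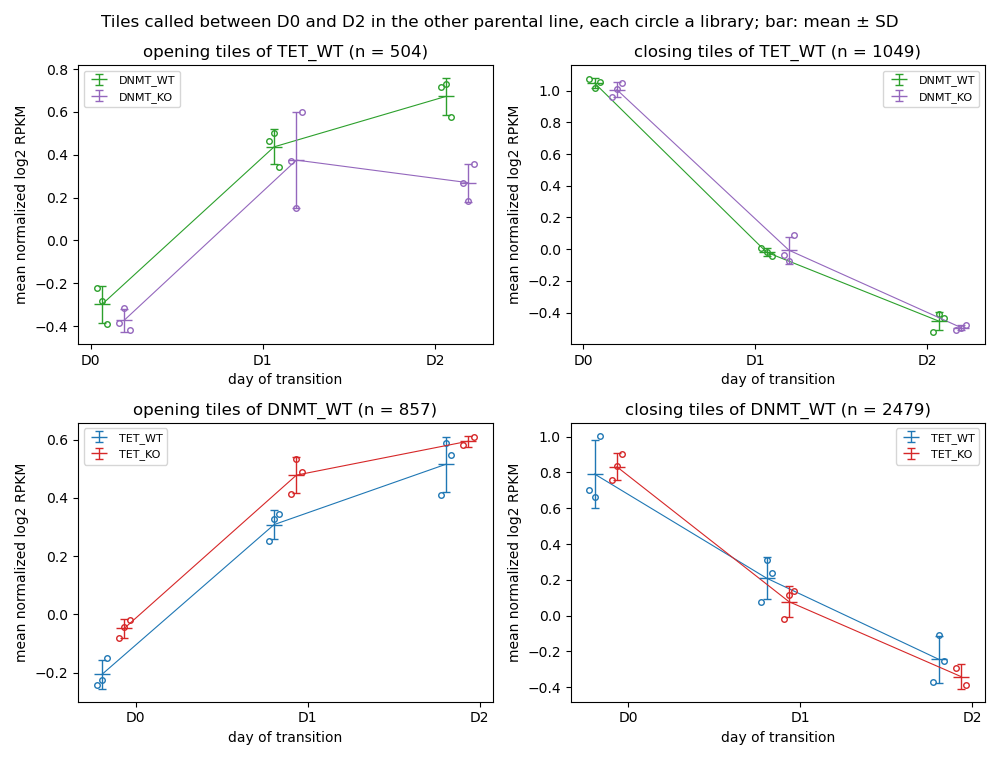
Mean log2 RPKM per library of the tiles that opened or closed in the other parental line, by day and line, 1 point per library, with group mean and SD. At D2 the opening tiles stand at 0.27 in DNMT_KO and 0.67 in DNMT_WT, and the closing tiles at -0.49 and -0.45.

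The knockouts of the TET enzymes and of the DNA methyltransferases were then set against each other, since their comparisons share no libraries. Across tiles, the log2 differences of TET_KO and DNMT_KO from their parents correlated with Pearson's r of -0.04 at D0, 0.00 at D1 and -0.11 at D2 (Spearman's rho -0.04, 0.00 and -0.11; tiles are not independent replicates). At D1, 1 tile was higher in both knockouts, and 0 tiles were called in both in the same direction otherwise, against 0.0232 or fewer in independent lists. That tile, named here after its values were seen, was the promoter end of the predicted gene Gm17330 (chromosome 12, 23968001 to 23970000), at 1.49 ± 0.32 in TET_KO (7 reads over the TET_KO libraries against 0) and 2.30 ± 0.32 in DNMT_KO (9 against 1). With 0 or 1 read in the parental libraries these values depend on the value given to an empty tile. The count was 0 with thinned reads, without the tiles empty at D0 and D2, on the values as deposited, after median centring or with limma voom, and 2 with the highest 5% or 20% of tiles. Without a filter 98 tiles were higher in both (78.1 in independent lists) and 33 lower (4.98).

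The parental lines were compared at D0, where the sum over tiles was 1.15 times the library total behind the RPKM in TET_WT and 1.02 times in DNMT_WT. The families were thus processed differently at D0, and the D0 libraries alone cannot tell line apart from processing. Among naive neighbourhoods 2 of 21 were higher and 4 lower in DNMT_WT (4 and 4 over the list alone; mean -0.06, adjusted p = 0.908). Among them were Klf5 (-0.81 ± 0.14), Nanog (-0.80 ± 0.13), Gbx2 (0.71 ± 0.16), a homeobox gene on chromosome 1, and Tfcp2l1 (0.66 ± 0.15), also on chromosome 1. Background density differed between lines by chromosome. Chromosome 1 stood at 0.43 ± 0.04 log2 units in DNMT_WT and -0.13 ± 0.08 in TET_WT (SD, n = 9 libraries each), a ratio of 1.48, and chromosome 14 at -0.26 and 0.24, a ratio of 0.705. Chromosome 8 stood at -0.11 ± 0.06 in TET_KO (n = 8), 0.34 ± 0.06 in TET_WT, 0.35 in DNMT_WT and 0.38 in DNMT_KO, and the TET_KO to TET_WT ratio was 0.732 on chromosome 8 and 0.781 on chromosome 14. After density centring Gbx2 was 0.13, Tfcp2l1 0.07, Klf5 -0.26 and Nanog -0.51, none called, and 3 of 29 list-gene calls were left, among them the imprinted gene Impact (-0.97 ± 0.21, then -0.92) and Olig2 (-0.84 ± 0.15, then -0.80). Tfcp2l1 was lost without 1 library (adjusted p = 0.0596 without TET_WT D0 replicate 1), and of the 29 calls 5 were kept as deposited, 6 with thinned reads and 0 with only these groups in the fit. MAPK response (mean -0.31, adjusted p = 0.0124) and housekeeping genes (mean -0.32, adjusted p = 0.0124) were lower and fibroblast genes higher (mean 0.46, adjusted p = 0.0175) by camera. They had adjusted p = 0.0576, 0.208 and 0.208 with an estimated correlation. The fibroblast test gave adjusted p = 0.12 without TET_WT D0 replicate 1 and 0.0785 without DNMT_WT D0 replicate 1 and 0.0566 after density centring. The other 14 lists had adjusted p of 0.0739 or more. Of the alternative settings 10 of 13 passed for MAPK response genes, 9 of 13 for housekeeping genes and 6 of 13 for fibroblast genes (adjusted p up to 0.0776, 0.134 and 0.829). By tile, 1115 differed, 652 higher and 463 lower in DNMT_WT, and 243 after density centring. The count was 211 (133 higher) without TET_WT D0 replicate 1, 172 (119) without replicate 2, 461 (177) without DNMT_WT D0 replicate 1 and 371 (176) without replicate 2, and ranged from 33 with thinned reads to 4410 with limma voom. The share of higher calls was 58.5%, 26.1% as deposited and 44.9% median-centred.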

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

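The counts over other splits of the samples were planned beforehand, and the other tests of explanations in this part were chosen after the results had been seen. Differences between lines in the change from D0 to D2 were picked out by the interaction test.

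The lower tiles of TET_KO at D0 lay mostly on chromosome 8 (147 of 189). The background read density of chromosome 8 differed from TET_WT by -0.45 log2 units, as a line with fewer copies of this chromosome would show. It stood at -0.11 in TET_KO, 0.34 in TET_WT, 0.35 in DNMT_WT and 0.38 in DNMT_KO, so that the gap may be a gain in the other lines that TET_KO lacks as well as a loss in TET_KO. A loss of accessibility beyond the density stays open too: read in the D1 and D2 libraries, which did not choose them, the 147 tiles differed by -0.72 and -0.69, and after density centring by -0.24 (SD of the libraries 0.07) and -0.25 (SD 0.09). At D0 their median fold went from -1.80 to -1.37, and 5 of the 147 stayed called, against 19 of the 42 lower tiles of other chromosomes, while neither copies by another method nor the loss of the TET enzymes as a source was tested.

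Formative neighbourhoods changed less from D0 to D2 in TET_KO than in TET_WT (mean -0.27; camera adjusted p = 0.000326). A steady copy number cancels in this change, so density centring is no test. It left adjusted p = 0.000593 (0.0404 with an estimated correlation). A slower exit from the naive state would leave naive genes higher at D2, and they were lower (-0.23, past the threshold), though they were lower at D0 as well. Depth stays open: thinned reads left -0.21 with adjusted p = 0.0485 (0.174 with an estimated correlation), where fewer reads alone raise a p. As DNMT_WT rose less than TET_WT, a trait of TET_WT stays open. The loss of the TET enzymes stays open and untested, with 2 TET_KO libraries at D2.

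Tiles that open in TET_WT stood lower in DNMT_KO than in DNMT_WT at D2 (-0.40). Depth is argued against by the thinned reads (-0.40), and a lower share of reads in open tiles by the lowest DNMT_KO library (24.9%, against 24.2 to 26.3% in DNMT_WT). A general delay by the missing share of the gain (34%) would leave closing tiles 0.51 higher in DNMT_KO, and they differed by -0.0411 (0.0215 on the values as deposited). Chance stays open, since 3 against 3 libraries allow no exact p below 0.1, and the change from D0 to D2 gave p = 0.105. The loss of the methyltransferases itself stays open and untested.

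A tile near Trps1 differed between the TET lines in its change (-3.75 ± 0.61), with 0 and 8 reads in TET_KO at D2, 33, 34 and 44 at D0, 19, 19 and 31 in TET_WT at D2 and 72, 17 and 58 at D0. A tile inside Pitpnc1 did so too (-3.59 ± 0.66; 1 and 4 reads in TET_KO at D2 and 30, 20 and 29 in TET_WT). The Peg3 tile (-2.30 ± 0.33) had -0.66 without the tiles empty at D0 and D2. Core pluripotency and methylation machinery neighbourhoods also changed differently (means -0.21 and -0.22, camera adjusted p = 0.035 and 0.0149). With an estimated correlation adjusted p was 0.196 and 0.0696, and they passed in 6 and 9 of 13 alternative settings.

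For comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. In 1 of the 10, the real one, as many tiles were called as in the real split for TET_WT at D1 (519, highest other 21) and D2 (1558, 85), DNMT_WT at D1 (1683, 5) and D2 (3355, 6), TET_KO at D0 (349, 3) and D1 (165, 4), DNMT_KO at D2 (39, 6) and the parental lines at D0 (1115, 18). For DNMT_KO it was 2 of 10 at D1 (58, highest other 74) and 7 of 10 at D0 (1, 3). Of 100 splits for the DNMT interaction, 27 gave at least the real count of 1, so chance is not excluded. The highest other gave 37, and what sets such a count was not tested.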

How the results depend on the processing

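The fits with chromosomes centred on mean density, limma voom, thinned reads, no D1 libraries or no tiles empty at D0 and D2 were chosen after the data were seen, as was the change of scores from D0 to D2, and the others were planned. Over 896 results and 18125 alternatives, 14194 kept direction and side of the threshold, 2569 kept direction without passing, 1362 moved as a count or value and 0 called results turned direction by their own test. Scores that had passed no test did change sign as deposited (TET opening at D1 and D2, DNMT closing at each day and in its change), after median centring (DNMT closing at D0, D1 and in its change) or with a library left out, and the naive means at D1 lay above 0 as deposited, where their tests did not pass. The naive and formative list tests of both parental lines at D2, and the naive, formative and MAPK response tests of TET_KO at D2, passed in every alternative run. Counts of single tiles depended on the setting, and of the list-gene neighbourhoods called in each comparison 0 were called when only its groups entered the fit. Of 53 called list tests, 18 passed in every alternative setting, 26 whichever library was left out and 16 in both. The shift of the D1 libraries and the few ranks raised by D1-only tiles account for part of this by construction, as do fewer samples in the smaller fits, and for the rest the cause was not tested. Depth limits the tile tests, since thinning every library to the reads of the shallowest gave 11 to 40 calls in TET_KO and 0 to 3 in DNMT_KO. The GC correction, alone and with the block, was not run.

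On the values as deposited tile counts were 5868 for TET_WT at D1, 311 for TET_WT at D2, 8868 for DNMT_WT at D1, 2210 for DNMT_WT at D2 and 36 for TET_KO at D0. It gave 263 for TET_KO at D1, 43 for TET_KO at D2, 0 for DNMT_KO at D0, 104 for DNMT_KO at D1 and 8 for DNMT_KO at D2. There were 0 for the TET interaction, 0 for the DNMT interaction and 130 for the parental lines. The TET opening score then differed by 0.0296 at D0, -0.0755 at D1 and -0.0558 at D2. The TET closing score then differed by -0.41 at D1, -0.265 at D2 and -0.31 from D0 to D2. The DNMT closing score then differed by 0.0664 at D0, -0.0588 at D1, 0.0215 at D2 and -0.0449 from D0 to D2. After median centring tile counts were 186 for TET_WT at D1, 471 for TET_WT at D2, 1112 for DNMT_WT at D1, 56 for TET_KO at D0 and 45 for TET_KO at D2. It gave 0 for DNMT_KO at D0, 467 for DNMT_KO at D1, 7 for DNMT_KO at D2, 0 for the TET interaction and 0 for the DNMT interaction. There were 167 for the parental lines. The TET opening score then differed by 0.12 at D0. The TET closing score then differed by -0.28 from D0 to D2. The DNMT closing score then differed by 0.0113 at D0, -0.12 at D1 and -0.0482 from D0 to D2. With the highest 5% of tiles tile counts were 206 for TET_KO at D0, 0 for DNMT_KO at D0, 30 for DNMT_KO at D1, 18 for DNMT_KO at D2 and 0 for the DNMT interaction. It gave 709 for the parental lines. Without a filter on tiles tile counts were 2020 for TET_WT at D1, 116 for TET_WT at D2, 3132 for DNMT_WT at D1, 1300 for DNMT_WT at D2 and 47 for TET_KO at D0. It gave 2249 for TET_KO at D1, 31 for TET_KO at D2, 21 for DNMT_KO at D0, 82393 for DNMT_KO at D1 and 0 for DNMT_KO at D2. There were 0 for the TET interaction, 6 for the DNMT interaction and 86 for the parental lines. With a pseudocount of 0.5 tile counts were 90 for TET_KO at D2, 2 for DNMT_KO at D0, 32 for DNMT_KO at D1, 23 for DNMT_KO at D2 and 1 for the TET interaction. With only the groups of a contrast in the fit tile counts were 248 for TET_WT at D1, 866 for TET_WT at D2, 1060 for DNMT_WT at D1, 777 for DNMT_WT at D2 and 12 for TET_KO at D0. It gave 76 for TET_KO at D1, 16 for TET_KO at D2, 3 for DNMT_KO at D0, 0 for DNMT_KO at D1 and 6 for DNMT_KO at D2. There were 0 for the DNMT interaction and 56 for the parental lines. With chromosomes centred on medians tile counts were 62 for TET_KO at D0, 65 for TET_KO at D1, 44 for TET_KO at D2, 0 for DNMT_KO at D0 and 29 for DNMT_KO at D1. It gave 1 for the TET interaction, 0 for the DNMT interaction and 210 for the parental lines. With chromosomes centred on mean density tile counts were 84 for TET_KO at D0, 69 for TET_KO at D1, 48 for TET_KO at D2, 0 for DNMT_KO at D0 and 24 for DNMT_KO at D1. It gave 0 for the DNMT interaction and 243 for the parental lines. With limma voom on the recovered reads tile counts were 2748 for TET_WT at D1, 7155 for TET_WT at D2, 860 for DNMT_WT at D1, 1402 for DNMT_WT at D2 and 2534 for TET_KO at D0. It gave 330 for TET_KO at D2, 0 for DNMT_KO at D1, 1 for DNMT_KO at D2, 1 for the TET interaction and 0 for the DNMT interaction. There were 4410 for the parental lines. With reads thinned to 1 depth tile counts were 77 for TET_WT at D1, 145 for TET_WT at D2, 155 for DNMT_WT at D1, 526 for DNMT_WT at D2 and 11 for TET_KO at D0. It gave 40 for TET_KO at D1, 22 for TET_KO at D2, 0 for DNMT_KO at D0, 3 for DNMT_KO at D1 and 1 for DNMT_KO at D2. There were 0 for the TET interaction, 0 for the DNMT interaction and 33 for the parental lines. The TET opening score then differed by 0.0912 at D0. Without the D1 libraries tile counts were 151 for TET_KO at D0, 49 for TET_KO at D2, 0 for DNMT_KO at D0, 1 for DNMT_KO at D2 and 0 for the TET interaction. It gave 0 for the DNMT interaction and 687 for the parental lines. Without the tiles empty at D0 and D2 tile counts were 0 for DNMT_KO at D0, 9 for DNMT_KO at D1 and 0 for the DNMT interaction. Tiles higher in both knockouts at D1 numbered 0 on the values as deposited, after median centring, with limma voom, with thinned reads and without the tiles empty at D0 and D2. They numbered 2 with the highest 5% or 20% of tiles and 98 without a filter, where 33 were lower in both. The imprinted test of DNMT_KO at D0 gave adjusted p = 0.29 without a filter on tiles, 0.254 with thinned reads and 0.0553 without the tiles empty at D0 and D2. The formative test of the TET interaction gave adjusted p = 0.166 without a filter on tiles. With a replicate block the counts were 2 for DNMT_KO at D0 and 2 for the DNMT interaction, and no other count moved by over 1.5 times. Deviations of same-numbered compared libraries correlated at -0.142 to 0.167 across tiles, which read noise lowers, so pairing is unknown. Leaving out 1 library at a time, tile counts ranged from 175 to 404 for TET_WT at D1, 727 to 1120 for TET_WT at D2, 857 to 1272 for DNMT_WT at D1, 2052 to 2575 for DNMT_WT at D2, 52 to 675 for TET_KO at D0, 78 to 252 for TET_KO at D1 and 50 to 394 for TET_KO at D2. They ranged from 1 to 5 for DNMT_KO at D0, 65 to 900 for DNMT_KO at D1, 22 to 77 for DNMT_KO at D2, 1 to 14 for the TET interaction, 1 to 3 for the DNMT interaction and 172 to 1346 for the parental lines. The imprinted test in DNMT_KO ranged from 0.0109 to 0.218 at D0 and at promoter ends from 0.000574 to 0.0656 at D2. The closing score of the TET change ranged from -0.24 to -0.0683. Where a group was left with 1 library, that library was assumed to vary like the other groups.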

Other observations

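The tests at promoter ends were planned, while the choice of genes with clear ends and the look at principal components were made after the data were seen. At promoter ends, read apart from the rest of each neighbourhood, naive genes closed in both parental lines from D0 to D2. In TET_WT 2 of 18 fell and 0 rose (2 and 0 when adjusted over the list alone, mean -0.29, camera adjusted p = 0.000308), and in DNMT_WT 2 and 0 (3 and 0, mean -0.40, adjusted p = 0.000339). The same 2 genes fell in both lines, Tdh (-1.79 ± 0.38 in TET_WT and -1.79 ± 0.38 in DNMT_WT) and Tfcp2l1 (-1.20 ± 0.28 and -1.16 ± 0.28). Formative promoter ends opened in TET_WT (2 of 17 rose and 0 fell, mean 0.46, adjusted p = 0.000273). In DNMT_WT they had a mean of 0.35 (adjusted p = 0.0524), and the difference between the lines was not tested. The 2 naive tests and that of formative genes in TET_WT passed in every alternative setting and whichever library was left out, and with an estimated correlation. The promoter end of Tdh was lost in TET_WT without 1 library (adjusted p = 0.0726 without TET_WT D2 replicate 3) and in DNMT_WT without 1 (0.0524 without DNMT_WT D0 replicate 1). That of Tfcp2l1 was lost in TET_WT in 3 of 6 fits (adjusted p = 0.0646 without TET_WT D0 replicate 1, 0.0717 without replicate 3 and 0.12 without TET_WT D2 replicate 1) and in DNMT_WT in 2 of 6 fits (0.0578 without DNMT_WT D0 replicate 2 and 0.0912 without DNMT_WT D2 replicate 1).

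Other promoter-end tests of TET_WT passed at the preset correlation only. At D2, core pluripotency (0.36), neuroectoderm (0.36), imprinted (0.31) and MAPK response genes (0.29) had camera adjusted p = 0.0316, 0.0281, 0.0335 and 0.0281, and 0.0628, 0.0591, 0.0628 and 0.0628 with an estimated correlation. They passed in 11, 11, 9 and 11 of 13 settings. The core and MAPK tests did not pass without D0 replicate 3 or D2 replicate 1 or 3 (adjusted p up to 0.261 and 0.142), the neuroectoderm test without D0 replicate 2 or D2 replicate 3 (0.0688) and the imprinted test without D0 replicate 1 or 2 or D2 replicate 1 or 3 (0.0925). At D1, processed differently, naive (-0.21) and formative genes (0.30) had adjusted p = 0.0267 and 0.048, and 0.187 with an estimated correlation, each passing in 9 of 12 settings. Of the fits without 1 library, naive genes passed only without D0 replicate 2 or D1 replicate 3 and formative genes only without D0 replicate 2 (otherwise adjusted p up to 0.141 and 0.166).

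Over all tested tiles, the first principal component (8.88% of variance) placed all 17 libraries of the TET family on 1 side of 0 and all 18 of the DNMT family on the other, and the families were processed differently at D0 and D2. The second (8.71%) placed all 12 libraries of D0 above all 23 libraries of D1 and D2. At D2 all DNMT_KO libraries lay below those of DNMT_WT on the first, and the other 5 pairs of knockout and parent overlapped on both. On the fourth (4.61%) every TET_KO library lay below TET_WT at each day.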
